A study of Mus musculus with 12 samples.

How the data were processed

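The series measured messenger RNA in mouse Th17 cells, a class of interleukin-17-producing helper T cell made in culture. Per the labels' protocols, naive CD4+ T cells from wild-type mice were activated on plates coated with antibodies to CD3 and CD28 for 72 h. The medium held TGF-B, IL-6 and antibodies that block interferon gamma and IL-4. The cells were left untreated or were given dexamethasone (Dex, a synthetic glucocorticoid), interleukin-1 beta (IL-1B), or both, for the 4 h before harvest. The 4 groups held 3 samples each, 12 in all. RNA was extracted with Trizol, selected with poly-T beads, fragmented, copied from random primers and amplified by PCR without any molecular identifier that the labels mention.

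The authors deposited 1 table of raw read counts per gene, whole numbers that were not normalized, with 12 columns of values, of which 0 were not used. Per the submitters' processing notes the tools were STAR 2.7.0a, HTSeq 0.6.1 and DESeq2, and the builds GRCm38 and mm10, with no role or setting given for any of them. No strand setting is given in the sources used here, so reads from a gene and from an overlapping or antisense gene cannot be told apart, and the counting could have split reads between near-identical copies. The table held 35275 gene identifiers, of which 34490 matched a symbol in the GENCODE annotation of GRCm38 used here. It held 0 lines that named no gene. Total counts per sample ran from 16904106 to 30445734, and counting error is therefore small for all but the lowest genes. Reads copied by PCR are not independent molecules, so these totals bound counting error only.

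Differential expression was tested in R 4.3.3 with edgeR 4.0.16. Counts were scaled with TMM factors, genes were kept by the edgeR filter on group, and 13821 genes were tested. Genes left out held 0.0563% of all counts. A one-way model over the 4 groups was fitted by robust quasi-likelihood, with 8 residual degrees of freedom, and 6 contrasts were tested: the 5 comparisons between groups described in the report, and the interaction of Dex and IL-1B. Adjusted p-values are Benjamini-Hochberg values over the genes tested in one contrast, from edgeR unless another tool is named, and a gene was called at an adjusted p under 0.05. Log2 fold changes are given ± SE, with n = 3 in each group, and CPM values (counts scaled by TMM library sizes) ± SD. The labels do not say that the 3 samples of a group came from separate cultures or mice, so all p-values measure only the spread between these samples, which may be technical.

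The contrasts, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. Named genes were, per comparison, the 6 largest rises and the 6 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between the replicates of the groups compared, leaving out names that are only a clone or model number, pseudogenes and antigen receptor segments. To these were added a panel of 18 genes of glucocorticoid, IL-1 and Th17 biology, given whatever their values, and up to 4 members with the smallest adjusted p of each list described. Results of some of these genes are not reported here. Members with under 4 reads in a group compared are not named for their fold change. Il10, on the panel, was not tested, since its raw counts were 2 to 10 per sample.

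Gene lists were fixed from general knowledge of T cells, glucocorticoids and IL-1, 27 in all, of which 26 had the minimum of 5 tested members. They were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists in a contrast, and again with an estimated correlation and with fry. At the preset correlation, camera takes the genes of a list to move almost independently. A list is called higher or lower by the direction of its test, which does not give the direction of each member. Fry tests whether the genes of a list move, on balance, one way, and compares the list with no other genes.

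The scripts were tested on simulated data for the real genes and libraries, with 200 genes changed by a known amount. For Dex against untreated, over 13821 genes, 31.3% of 67 genes changed 1.5-fold, 70.1% of 67 changed 2-fold and 87.9% of 66 changed 4-fold were called, with 7 unchanged genes called. The interaction was recovered for 9%, 50.7% and 74.2% of the genes at those sizes, with 1 unchanged gene called. The simulated genes varied independently of each other, so these shares may be too high for real libraries that differ in many genes at once.

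Alternatives were DESeq2 1.42.0, limma-voom, median-ratio scaling, 2 other filters on low counts, a test against a 1.5-fold change, a fit to only the groups compared, the replicate number as a block, and each of the 12 libraries left out in turn. DESeq2 gave no adjusted p for 1342 genes in the contrasts of Dex against untreated and of both against Dex, for 538 in that of both against untreated and for 2 in each of the other contrasts, and these were not counted as called. The fit without 2 libraries that stand apart in counts for rRNA-overlapping genes was added after seeing the data. Overlaps between comparisons that share libraries were set beside 20 simulations with no effect.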

Results

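Dexamethasone, a glucocorticoid that represses many inflammatory genes, and IL-1B, a cytokine that acts on Th17 cells through its receptor Il1r1, were given to mouse Th17 cells alone or together. The design asks what each agent did alone, what they did together, and whether one changed the effect of the other. Counts came from 4 groups of 3 libraries, named here by group and replicate number (untreated 1 is replicate 1 of the untreated group). Total counts were 24215652, 30445734 and 20272945 in untreated 1, 2 and 3 and 22900971, 21850738 and 24106318 with Dex. They were 20028057, 19929403 and 17151850 with IL-1B and 16904106, 23543887 and 23986359 with both.

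The libraries differed first by IL-1B. On a principal component analysis of log2 CPM the first component, with 35.4% of the variance, held all 6 libraries with IL-1B between 12.08 and 42.14 and the other 6 between -35.32 and -18.34. The second component, with 16.7%, spread libraries of one group, with untreated 1 at -39 and untreated 3 at 3.01. In IL-1B 2 and Dex+IL-1B 1 the genes that overlap ribosomal RNA repeats (Gm42418, Gm26917 and Lars2) held 12743 and 17399 CPM, against 2321 to 5777 CPM in the other 10 libraries. The correlation of log2 CPM across genes was 0.978 to 0.992 between replicates, and no pair of replicates agreed within sampling noise, with a chi-square per degree of freedom of 4.48 to 53.08.

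**Figure D1:**
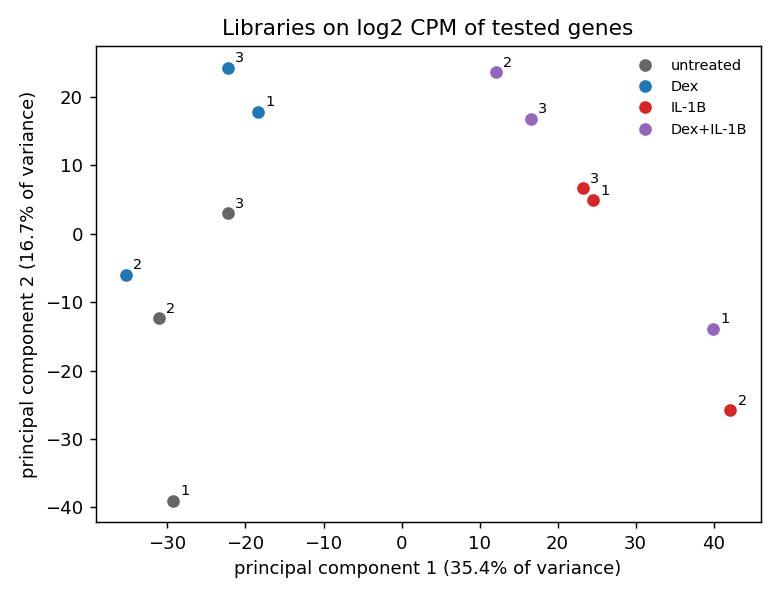
Principal components 1 and 2 of log2 CPM over the tested genes, with 1 point per library, coloured by group and labelled by replicate number. Component 1 (35.4% of the variance) separates the libraries with IL-1B (12.08 to 42.14) from those without (-35.32 to -18.34), and untreated 1 lies lowest on component 2 at -39.

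Dex alone raised known glucocorticoid-induced genes and lowered the chemokine gene Ccl20, with less firm falls of Ccl3 and Ccl4. Klf9, a transcription factor gene driven by the glucocorticoid receptor, rose by 1.40 ± 0.10 (log2, adjusted p = 1.00e-05), from 17.8 ± 1.07 to 47.2 ± 2.65 CPM. Fkbp5, a co-chaperone of that receptor, rose by 1.12 ± 0.10 (adjusted p = 4.83e-05), and Pdcd4, an inhibitor of translation, by 1.25 ± 0.10 (adjusted p = 3.30e-05). The largest rise by the rule was that of Plaur, the urokinase receptor (2.83 ± 0.37, adjusted p = 0.00346). Ccl20, a chemokine that recruits CCR6-bearing cells such as Th17 cells, changed by -1.46 ± 0.11 (adjusted p = 1.06e-05), from 50.3 ± 1.43 to 18.2 ± 0.480 CPM, and the semaphorin Sema6d by -1.39 ± 0.16 (adjusted p = 0.000930). On GRCm38 these genes were Klf9 (ENSMUSG00000033863, chromosome 19, 23141226 to 23168134), Fkbp5 (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527), Pdcd4 (ENSMUSG00000024975, chromosome 19, 53892231 to 53929860) and Ccl20 (ENSMUSG00000026166, chromosome 1, 83116766 to 83119167). In all, 74 of the 13821 genes tested were called, 51 higher and 23 lower, of which 25 changed at least 2-fold. That count was 17 without untreated 1, 16 without untreated 2, 17 without Dex 1, 253 without Dex 2, 17 without Dex 3, 121 without IL-1B 2 and 42 without Dex+IL-1B 3. DESeq2 called 281 genes, edgeR with no low-count filter 138, and a test against a 1.5-fold change 7. A split of the same libraries other than by treatment, untreated 1, untreated 2 and Dex 2 against untreated 3, Dex 1 and Dex 3, called 257.

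**Figure D2:**
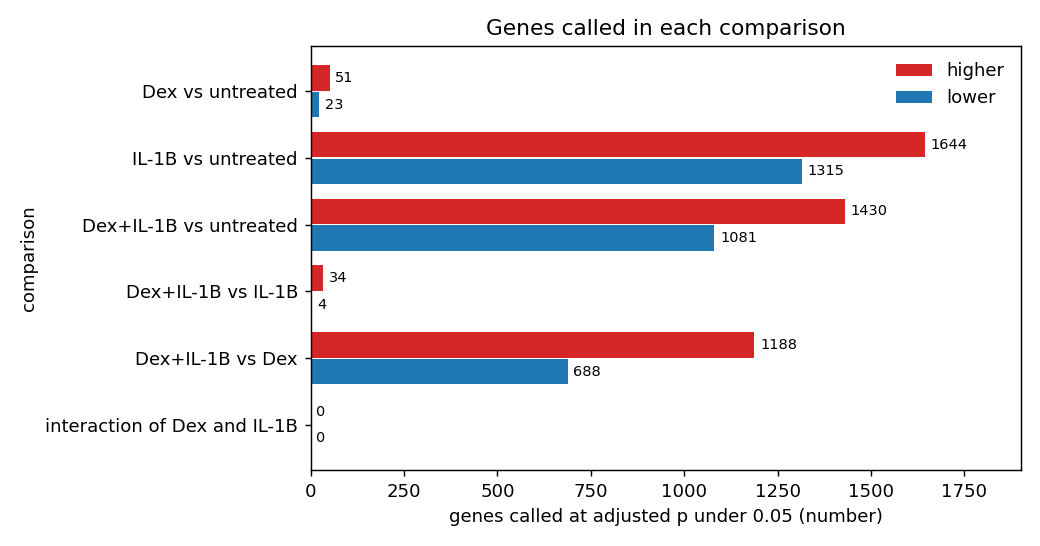
Number of genes called at an adjusted p under 0.05 by edgeR in each comparison, higher (red) and lower (blue) in the first group named, out of 13821 tested. IL-1B against untreated gave 1644 higher and 1315 lower, Dex against untreated 51 and 23, and the interaction 0 and 0.

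The remaining genes of the rule for Dex alone were called less firmly. Rises were those of Ramp3 (2.81 ± 0.52, adjusted p = 0.0350), Ston1 (1.43 ± 0.22, adjusted p = 0.00987) and Dysf (1.38 ± 0.26, adjusted p = 0.0319). Falls were those of Ccl3 and Ccl4, chemokine genes of a multigene family whose reads could be split between copies, at -2.11 ± 0.32 (adjusted p = 0.0103) and -1.12 ± 0.23 (adjusted p = 0.0427). Lower too were the Th17 cytokine Il17f (-1.27 ± 0.23, adjusted p = 0.0350) and Tgtp1 (-1.09 ± 0.20, adjusted p = 0.0319), which has a near-identical copy that could share its reads. Ramp3 was not called without untreated 1, untreated 2, Dex 1, Dex 3, IL-1B 1, IL-1B 3 or Dex+IL-1B 3 (adjusted p = 0.184, 0.222, 0.178, 0.163, 0.0509, 0.0641 and 0.0619, and 2.18e-06 to 0.222 over all alternatives). Ston1 lost its call without untreated 1 or untreated 2 (adjusted p = 0.0808 and 0.0752, and 3.14e-07 to 0.113 over all alternatives). Dysf was not called without untreated 1, untreated 2, Dex 1, Dex 3 or Dex+IL-1B 3 (adjusted p = 0.163, 0.153, 0.145, 0.102 and 0.0501, and 7.47e-05 to 0.163 over all alternatives). For Ccl3 the call was lost without Dex 1 or Dex 3 (adjusted p = 0.0899 and 0.0747, and 1.02e-07 to 0.0899 over all alternatives). Ccl4 was not called without untreated 1, untreated 2, untreated 3, Dex 1, Dex 3, IL-1B 3, Dex+IL-1B 2 or Dex+IL-1B 3 (adjusted p = 0.193, 0.172, 0.0615, 0.178, 0.281, 0.0507, 0.0707 and 0.0577, and 0.000372 to 0.281 over all alternatives). Il17f was not called without untreated 1, untreated 2, Dex 1, Dex 3, IL-1B 1, IL-1B 2, IL-1B 3 or Dex+IL-1B 3 (adjusted p = 0.0808, 0.0836, 0.208, 0.182, 0.0549, 0.0735, 0.0583 and 0.0595, and 5.08e-06 to 0.208 over all alternatives). Tgtp1 lost its call without untreated 1, untreated 2, Dex 1, Dex 3 or Dex+IL-1B 3 (adjusted p = 0.145, 0.141, 0.175, 0.199 and 0.0501, and 4.68e-05 to 0.199 over all alternatives).

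Of the panel, Tsc22d3, a glucocorticoid-induced leucine zipper gene, had 1.41 ± 0.48 with Dex alone (adjusted p = 0.328), not past the threshold, with 111 ± 36.8 CPM against 41.8 ± 7.61 in untreated libraries. Nor were Nfkbia (-0.50 ± 0.12, adjusted p = 0.0888), Il17a (-0.75 ± 0.31, adjusted p = 0.443) and Il1r1 (-0.91 ± 0.36, adjusted p = 0.425) called. Positive values without a call were those of Nfkbiz (0.53 ± 0.23, adjusted p = 0.464), Dusp1 (0.38 ± 0.14, adjusted p = 0.338) and Nr3c1 (0.19 ± 0.12, adjusted p = 0.658). Nfkbia, the NF-kB inhibitor gene, was called lower without untreated 3, Dex 2 or IL-1B 2 (adjusted p = 0.0472, 0.0372 and 0.0351, and 0.00523 to 0.482 over all alternatives). Smaller or noisier values were those of Foxp3 (0.17 ± 0.28), Il1r2 (0.03 ± 0.15), Tnfaip3 (-0.03 ± 0.13), Il23r (-0.06 ± 0.18), Il22 (-0.21 ± 1.09), Ifng (-1.60 ± 0.96) and Csf2 (-2.02 ± 0.85), none called, with Il22, Ifng and Csf2 at 8, 4 and 7 reads over the Dex libraries.

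Among gene lists, 15 of 20 glucocorticoid-induced genes had positive values with Dex, and 3 of 21 NF-kB targets did. Of the glucocorticoid-induced genes 2 rose, 0 fell and 18 were not called, with 7 higher and 1 lower when adjusted over the list alone. Their median log2 change was 0.46 (adjusted p = 1.21e-12, and adjusted p = 0.0347 with an estimated correlation). Of the NF-kB targets 0 rose, 2 fell and 19 were not called, with 0 higher and 12 lower when adjusted over the list alone. The median log2 change was -0.26 (adjusted p = 1.09e-13, and adjusted p = 0.0347 with an estimated correlation). Nfkbie was the member called beside Ccl20, at -0.58 ± 0.10 (adjusted p = 0.0249). The Nfkbie call was lost without untreated 1, untreated 2, Dex 1 or Dex 3 (adjusted p = 0.134, 0.126, 0.155 and 0.182, and 0.000105 to 0.182 over all alternatives). Of 29 T cell cytokines and chemokines 0 rose, 5 fell and 24 were not called, with 2 higher and 9 lower when adjusted over the list alone. The list had a median of -0.34 (adjusted p = 6.41e-11, and adjusted p = 0.0347 with an estimated correlation), but -0.19 without Dex 2. The called ones were Ccl20, Ltb (-0.51 ± 0.08, adjusted p = 0.0172), and Ccl3, Ccl4 and Il17f, whose calls were lost without the single libraries already named. Ltb was not called without untreated 2, Dex 1 or Dex 3 (adjusted p = 0.0949, 0.118 and 0.0976, and 1.02e-07 to 0.118 over all alternatives). Of 22 Th17 identity genes 0 rose, 2 fell and 20 were not called, with 0 higher and 3 lower when adjusted over the list alone. Over the list the median was -0.16 (adjusted p = 5.42e-06, and adjusted p = 0.0347 with an estimated correlation). The called ones were Ccl20 and Il17f. Both are also on the list of cytokines and chemokines, and Ccl20 on that of NF-kB targets, so the falls of these lists are not independent. Of 12 Th1 genes 0 rose, 0 fell and 12 were not called, with 0 higher and 3 lower when adjusted over the list alone. As a list, these genes had a median of -0.49 (adjusted p = 0.00316, and adjusted p = 0.0411 with an estimated correlation), but -0.22 without untreated 1 and -0.75 without Dex 2. Fry gave these 5 lists adjusted p = 0.00786 to 0.0101. Beside the falls in these lists, markers of some other cell types had medians below 0 with Dex, among them B cell markers (-0.54). Over 8 myeloid and dendritic cell markers the median was -0.55, and -0.085 without untreated 1, not called (adjusted p = 0.0529, and adjusted p = 0.306 with an estimated correlation). That list was called lower without untreated 2, untreated 3 or IL-1B 1 (adjusted p = 0.0160, 0.0119 and 0.0496, and 0.0119 to 0.344 over all alternatives). Over 7 CD8 and NK cell markers it was -0.31, and -0.159 without untreated 3, not called (adjusted p = 0.0717, and adjusted p = 0.0246 by fry). Over 5 gamma-delta T and innate lymphoid markers it was -0.04 (adjusted p = 0.921, with medians of -0.137 to 0.061 over all alternatives). These were the members that could be tested of 18 myeloid, 12 CD8 and NK and 12 gamma-delta markers. The median over tested members of the highest group mean was 4.1, 5.6 and 3.5 CPM. Medians of these lists therefore say little about other cell types.

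The other 8 of the 13 lists called with Dex at the preset correlation lost the call with an estimated one. B cell markers, 11 tested, had a median of -0.54, and of -0.32 without untreated 1 (adjusted p = 1.66e-06, and adjusted p = 0.124 with an estimated correlation). Of these markers 0 rose, 0 fell and 11 were not called, with 0 higher and 6 lower when adjusted over the list alone. Ighm, an immunoglobulin gene, stood at 112.5 CPM in untreated 1, at 80.6 and 71 CPM in the other untreated libraries and at 54.4 to 68 CPM with Dex. Cell cycle genes were lower (median log2 change -0.15, adjusted p = 0.000614, and adjusted p = 0.296 with an estimated correlation). Lower too were Th17 genes associated with pathogenicity (median log2 change -0.20, but -0.13 without untreated 2 and -0.11 without Dex 1, adjusted p = 0.00937, and adjusted p = 0.0590 with an estimated correlation). That call was lost without Dex 2 (adjusted p = 0.0623, and 0.00166 to 0.0623 over all alternatives). Fry gave the pathogenicity list an adjusted p of 0.00786 and called no other of these 8 lists. Naive and homing genes were lower (median log2 change -0.20, but -0.10 without untreated 1, -0.32 without untreated 3 and -0.40 without Dex 2, adjusted p = 0.0200, and adjusted p = 0.434 with an estimated correlation). This call was lost without untreated 1, Dex 1, Dex 3 or Dex+IL-1B 1 or without the 2 libraries high in rRNA-overlapping genes (adjusted p = 0.445, 0.221, 0.0938, 0.0686 and 0.149, and 4.91e-05 to 0.445 over all alternatives). IL-1 receptor family genes were lower (median log2 change -0.11, but -0.18 without Dex 1, adjusted p = 0.0226, and adjusted p = 0.154 with an estimated correlation). Their call was lost without untreated 1 (adjusted p = 0.127, and 0.0138 to 0.154 over all alternatives). Cholesterol synthesis genes were lower (median log2 change -0.09, but -0.13 without untreated 1, -0.03 without untreated 3 and 0.011 without Dex 2, adjusted p = 0.0472, and adjusted p = 0.478 with an estimated correlation). The list lost its call without untreated 3, Dex 2 or Dex+IL-1B 3 (adjusted p = 0.791, 0.862 and 0.0516, and 0.000172 to 0.862 over all alternatives). Treg genes were higher (median log2 change 0.25, but 0.41 without untreated 3 and 0.16 without Dex 1, adjusted p = 0.00714, and adjusted p = 0.322 with an estimated correlation). The Treg call was lost without untreated 1 or Dex 1 (adjusted p = 0.133 and 0.0524, and 3.99e-05 to 0.322 over all alternatives). Glycolysis and hypoxia genes were higher (median log2 change 0.17, but 0.025 without untreated 1 and 0.11 without Dex 3, adjusted p = 0.00714, and adjusted p = 0.434 with an estimated correlation). Their call was lost without untreated 1 or Dex 3 (adjusted p = 0.682 and 0.0585, and 9.82e-05 to 0.682 over all alternatives).

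IL-1B alone changed far more genes, 2959 in all, 1644 higher and 1315 lower, of which 526 changed at least 2-fold. The Th17 cytokines rose, Il17a by 2.5 ± 0.31 (adjusted p = 0.000562), from 23.0 ± 8.06 to 130 ± 11.3 CPM, and Il17f by 2.01 ± 0.23 (adjusted p = 0.000304), from 120 ± 44.8 to 486 ± 19.0 CPM. Csf2, the gene of the cytokine GM-CSF, rose by 3.82 ± 0.57 (adjusted p = 0.000931) and the T cell growth factor Il2 by 3.56 ± 0.30 (adjusted p = 3.11e-05). Their loci on GRCm38 were Il17a (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496), Il17f (ENSMUSG00000041872, chromosome 1, 20777146 to 20790617) and Csf2 (ENSMUSG00000018916, chromosome 11, 54247271 to 54249667). Genes that fell included Klf2, a factor that keeps T cells in recirculation (-2.32 ± 0.33, adjusted p = 0.00106), and Il1r1, the signalling receptor of IL-1B itself (-2.22 ± 0.39, adjusted p = 0.00276). The count was 1609 without untreated 2, and a test against a 1.5-fold change called 127 genes.

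The largest rises with IL-1B by the rule were those of Mylk, a myosin kinase with 4 reads over the untreated libraries (6.71 ± 0.61, adjusted p = 2.69e-05), Lad1 (5.77 ± 0.47, adjusted p = 1.95e-05) and Pdzk1ip1 (4.65 ± 0.39, adjusted p = 1.76e-05). Csf2, Il2 and Sema3b (3.28 ± 0.51, adjusted p = 0.00137) came next. The largest falls by the rule were those of Klf2, Csf1 (-2.23 ± 0.49, adjusted p = 0.00851), Il1r1 and Scml4 (-2.08 ± 0.33, adjusted p = 0.00172). Lower too were Ifi209 (-2.18 ± 0.35, adjusted p = 0.00120) and Abcg3 (-1.99 ± 0.35, adjusted p = 0.00197), members of multigene families whose reads could be split between copies. Without the 2 libraries high in rRNA-overlapping genes, an alternative chosen after seeing the data, Csf1 had an adjusted p of 0.0746, within a range of 0.000480 to 0.0746 over its alternatives. Of the rest of the panel Ifng (3.19 ± 0.65, adjusted p = 0.00418), Il22 (2.97 ± 0.85, adjusted p = 0.0243) and Nfkbiz (1.55 ± 0.23, adjusted p = 0.00103) rose. So did Nfkbia (1.17 ± 0.12, adjusted p = 5.24e-05), Tnfaip3 (0.70 ± 0.13, adjusted p = 0.00309) and Il1r2 (0.61 ± 0.15, adjusted p = 0.0113). Lower was Tsc22d3 (-1.72 ± 0.51, adjusted p = 0.0367). Il22, at 10 reads over the untreated libraries, was not called without untreated 1, untreated 2, IL-1B 1 or IL-1B 3 (adjusted p = 0.0722, 0.0785, 0.0551 and 0.0501, and 0.00259 to 0.0785 over all alternatives). Il1r2 lost its call without untreated 2 (adjusted p = 0.0507, and 0.00224 to 0.0507 over all alternatives). Tsc22d3 was not called without untreated 1, untreated 2, IL-1B 1, IL-1B 2 or Dex+IL-1B 3 (adjusted p = 0.0745, 0.10, 0.0686, 0.0939 and 0.0519, and 0.0105 to 0.10 over all alternatives). Not called were Nr3c1 (-0.29 ± 0.12, adjusted p = 0.0982) and Fkbp5 (0.23 ± 0.10, adjusted p = 0.113). Neither were Il23r (-0.24 ± 0.18, adjusted p = 0.380), Dusp1 (-0.07 ± 0.14, adjusted p = 0.764) and Foxp3 (0.00 ± 0.28, adjusted p = 0.999). Nr3c1, the glucocorticoid receptor gene, was called lower without IL-1B 2 (adjusted p = 0.00945, and 0.00534 to 0.272 over all alternatives). Il23r was called lower without IL-1B 2 (adjusted p = 0.0229, and 0.0162 to 0.770 over all alternatives).

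**Figure D3:**
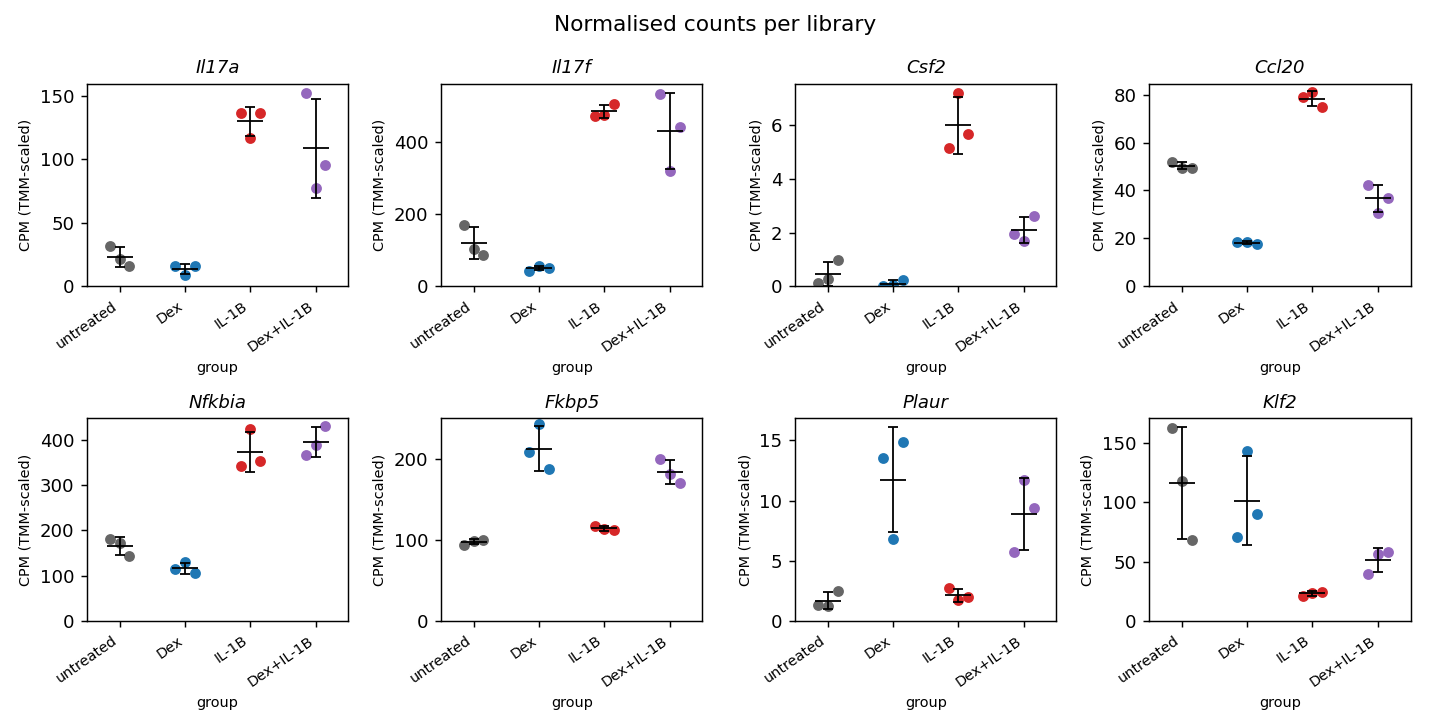
TMM-scaled CPM of 8 genes in each of the 12 libraries (points), with the group mean (line) and SD (bars, n = 3 per group). Il17a and Il17f stand at 130 ± 11.3 and 486 ± 19.0 CPM with IL-1B, against 23.0 ± 8.06 and 120 ± 44.8 in untreated libraries, and Ccl20 falls from 78.3 ± 3.10 to 36.6 ± 5.74 CPM where Dex was added to IL-1B.

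The list of NF-kB targets was called higher with IL-1B. Of the 21 tested 15 rose, 0 fell and 6 were not called, with 17 higher and 0 lower when adjusted over the list alone. Across the members the median was 0.70 (adjusted p = 3.93e-16, and adjusted p = 0.0470 with an estimated correlation), with Nfkb2 (1.40 ± 0.09, adjusted p = 7.28e-07) and Zc3h12a (1.32 ± 0.12, adjusted p = 2.40e-05) the smallest p-values. This was the one list called with an estimated correlation. Fry called 9 lists with IL-1B. Among them were NF-kB targets (adjusted p = 9.54e-05), and cytokines and chemokines, interferon-stimulated genes and cytokine receptors (adjusted p = 0.000639 for each of the latter). Fry did not call naive and homing genes (adjusted p = 0.0726). Of 29 T cell cytokines and chemokines 15 rose, 3 fell and 11 were not called, with 17 higher and 3 lower when adjusted over the list alone. Their median log2 change was 0.64 (adjusted p = 8.05e-08, and adjusted p = 0.0616 with an estimated correlation). Of 25 interferon-stimulated genes 0 rose, 10 fell and 15 were not called, with 1 higher and 11 lower when adjusted over the list alone. The median log2 change was -0.43 (adjusted p = 0.000380, and adjusted p = 0.0616 with an estimated correlation). Among them were Irf9 (-0.58 ± 0.09, adjusted p = 0.000749), Zbp1 (-0.92 ± 0.15, adjusted p = 0.00118) and Igtp (-0.65 ± 0.10, adjusted p = 0.00111), the last of a GTPase family with similar copies. Of 26 cytokine receptors 2 rose, 10 fell and 14 were not called, with 2 higher and 10 lower when adjusted over the list alone. The list had a median of -0.24 (adjusted p = 0.00828, and adjusted p = 0.0616 with an estimated correlation), with Tgfbr2 (-0.74 ± 0.12, adjusted p = 0.00159), Ifngr1 (-1.0 ± 0.18, adjusted p = 0.00275) and Il17ra (-1.03 ± 0.20, adjusted p = 0.00368) lower and Il2ra (0.67 ± 0.14, adjusted p = 0.00516) higher. Of 21 ATF4 and amino acid stress genes 10 rose, 0 fell and 11 were not called, with 14 higher and 0 lower when adjusted over the list alone. Over the list the median was 0.36 (adjusted p = 3.75e-05, and adjusted p = 0.504 with an estimated correlation), with the amino acid transporters Slc7a5 (0.94 ± 0.15, adjusted p = 0.00120) and Slc7a1 (0.97 ± 0.18, adjusted p = 0.00245). Of 17 naive and homing genes 1 rose, 6 fell and 10 were not called, with 1 higher and 6 lower when adjusted over the list alone. As a list, these genes had a median of -0.17 (adjusted p = 0.00369, and adjusted p = 0.588 with an estimated correlation), but -0.36 to -0.28 without any one of untreated 1, untreated 3, IL-1B 1, IL-1B 2 and IL-1B 3 or without the 2 libraries high in rRNA-overlapping genes, with S1pr1 (-1.75 ± 0.28, adjusted p = 0.00193) and Itgb7 (-0.80 ± 0.12, adjusted p = 0.000961) beside Klf2, while Satb1 (0.38 ± 0.09, adjusted p = 0.00855) rose.

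The remaining 3 lists called at the preset correlation with IL-1B were called less firmly. Fry gave adjusted p = 0.00681 for Th17 identity genes, 0.0434 for glucocorticoid receptor partners and 0.0843 for cholesterol synthesis genes. Of 22 Th17 identity genes 8 rose, 3 fell and 11 were not called, with 8 higher and 4 lower when adjusted over the list alone. Across the members the median was 0.07 (adjusted p = 0.0439, and adjusted p = 0.484 with an estimated correlation), but 0 to 0.18 without any one of untreated 1, untreated 3, IL-1B 1, IL-1B 2 and IL-1B 3 or without the 2 libraries high in rRNA-overlapping genes. The list call was lost without untreated 2, untreated 3, Dex 2 or IL-1B 2 or with a minimum of 1 CPM in 3 samples or without the 2 libraries high in rRNA-overlapping genes (adjusted p = 0.0548, 0.0899, 0.0700, 0.132, 0.0594 and 0.114, and 0.00681 to 0.484 over all alternatives). Called members included Batf (1.09 ± 0.14, adjusted p = 0.000311) beside the cytokines. Of 17 glucocorticoid receptor partners 6 rose, 0 fell and 11 were not called, with 7 higher and 3 lower when adjusted over the list alone. Their median log2 change was 0.21 (adjusted p = 0.0342, and adjusted p = 0.588 with an estimated correlation). The list call was lost without untreated 3 or IL-1B 2 (adjusted p = 0.0690 and 0.119, and 0.0103 to 0.588 over all alternatives). Called members included the co-chaperones Stip1 (0.85 ± 0.13, adjusted p = 0.000799) and Fkbp4 (0.67 ± 0.11, adjusted p = 0.00113). Of 23 cholesterol synthesis genes 8 rose, 0 fell and 15 were not called, with 11 higher and 1 lower when adjusted over the list alone. The median log2 change was 0.31 (adjusted p = 0.0347, and adjusted p = 0.598 with an estimated correlation). The list call was lost without untreated 1, IL-1B 1 or IL-1B 3 or with a minimum of 1 CPM in 3 samples (adjusted p = 0.242, 0.0619, 0.0813 and 0.0522, and 0.00298 to 0.598 over all alternatives). Called members included Hmgcs1 (0.41 ± 0.10, adjusted p = 0.00826). Th17 genes associated with pathogenicity went both ways, and of 18 tested 4 rose, 6 fell and 8 were not called, with 4 higher and 7 lower when adjusted over the list alone. Csf2 was higher and Ccl4 (-1.34 ± 0.23, adjusted p = 0.00171) and Lrmp (-0.77 ± 0.12, adjusted p = 0.00120) were lower beside Il1r1. Their median was -0.32, their mean 0.41 and the direction of the test down, not past the threshold (adjusted p = 0.476). Of 11 B cell markers 0 rose, 3 fell and 8 were not called, with 0 higher and 3 lower when adjusted over the list alone. Their median with IL-1B was -0.43, and -0.141 without untreated 1, not called (adjusted p = 0.0854). The B cell list was called lower without untreated 2 or untreated 3 (adjusted p = 0.0294 and 0.0190, and 0.0190 to 0.598 over all alternatives).

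Dex and IL-1B together gave 2511 called genes against untreated cells, 1430 higher and 1081 lower, of which 489 changed at least 2-fold. Il17a rose by 2.23 ± 0.30 (adjusted p = 0.000788) and Il17f by 1.84 ± 0.23 (adjusted p = 0.000356). Nfkbiz, an NF-kB cofactor, rose by 2.17 ± 0.23 (adjusted p = 0.000110), and the glucocorticoid-induced Fkbp5 by 0.92 ± 0.10 (adjusted p = 6.32e-05). The count was 1310 without untreated 2 and 1654 without Dex+IL-1B 3, and a test against a 1.5-fold change called 172.

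The largest rises with both agents by the rule were those of Mylk (6.92 ± 0.61, adjusted p = 1.80e-05, 4 reads over the untreated libraries), Lad1 (5.45 ± 0.47, adjusted p = 2.28e-05) and Pdzk1ip1 (4.62 ± 0.39, adjusted p = 1.29e-05). They were followed by Il24 (3.84 ± 0.96, adjusted p = 0.0183), Sema3b (3.74 ± 0.51, adjusted p = 0.000611) and Il2 (3.27 ± 0.30, adjusted p = 4.86e-05). By the rule the largest falls were those of Csf1 (-2.79 ± 0.51, adjusted p = 0.00372), Glrx (-2.17 ± 0.23, adjusted p = 9.39e-05) and Angptl2 (-2.06 ± 0.23, adjusted p = 0.000149). Others were those of Ifi209 (-2.14 ± 0.35, adjusted p = 0.00125), Ccl4 (-2.08 ± 0.24, adjusted p = 0.000110) and Mx1 (-2.06 ± 0.27, adjusted p = 0.000309), which belong to multigene families. Il24 was not called without untreated 1, untreated 2 or Dex+IL-1B 2 (adjusted p = 0.0560, 0.0743 and 0.0516, and 0.00363 to 0.0743 over all alternatives). Of the rest of the panel Il22 (3.06 ± 0.84, adjusted p = 0.0221), Ifng (2.43 ± 0.66, adjusted p = 0.0209) and Csf2 (2.31 ± 0.58, adjusted p = 0.0150) rose. So did Nfkbia (1.26 ± 0.12, adjusted p = 2.96e-05), Tnfaip3 (1.04 ± 0.13, adjusted p = 0.000259), Il1r2 (0.89 ± 0.15, adjusted p = 0.00154) and Dusp1 (0.43 ± 0.14, adjusted p = 0.0471). Lower was Il1r1 (-1.91 ± 0.38, adjusted p = 0.00578). Il22 was not called without untreated 1, untreated 2 or Dex+IL-1B 2 (adjusted p = 0.0677, 0.0765 and 0.0737, and 0.00191 to 0.0765 over all alternatives). Ifng lost its call without untreated 2, untreated 3 or Dex+IL-1B 3 (adjusted p = 0.105, 0.0589 and 0.0959, and 0.00165 to 0.105 over all alternatives). Csf2 was not called without untreated 2 or Dex+IL-1B 3 (adjusted p = 0.0811 and 0.0570, and 0.000195 to 0.0811 over all alternatives). Dusp1, near the threshold, lost its call without untreated 1, untreated 2, untreated 3, Dex 1, Dex 2, Dex 3, IL-1B 1, Dex+IL-1B 2 or Dex+IL-1B 3 (adjusted p = 0.0984, 0.0941, 0.127, 0.0758, 0.0524, 0.0541, 0.0600, 0.147 and 0.167, and 0.00404 to 0.167 over all alternatives). Not called were Tsc22d3 (0.38 ± 0.47, adjusted p = 0.640), Foxp3 (-0.02 ± 0.28, adjusted p = 0.973), Il23r (-0.14 ± 0.18, adjusted p = 0.637) and Nr3c1 (-0.20 ± 0.12, adjusted p = 0.258).

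With both agents the list of NF-kB targets was called higher and that of interferon-stimulated genes lower. Of 21 NF-kB targets 14 rose, 1 fell and 6 were not called, with 14 higher and 1 lower when adjusted over the list alone. The list had a median of 0.63 (adjusted p = 7.37e-14, and adjusted p = 0.0382 with an estimated correlation). Of 25 interferon-stimulated genes 0 rose, 8 fell and 17 were not called, with 0 higher and 9 lower when adjusted over the list alone. Over the list the median was -0.45 (adjusted p = 5.41e-06, and adjusted p = 0.0382 with an estimated correlation), with Zbp1 (-1.30 ± 0.15, adjusted p = 0.000108) among the latter. Of 20 glucocorticoid-induced genes 7 rose, 1 fell and 12 were not called, with 7 higher and 3 lower when adjusted over the list alone. As a list, these genes had a median of 0.40 (adjusted p = 0.00923, and adjusted p = 0.434 with an estimated correlation), but 0.21 without Dex+IL-1B 2. Of 29 cytokines and chemokines 10 rose, 4 fell and 15 were not called, with 11 higher and 4 lower when adjusted over the list alone. Across the members the median was 0.26 (adjusted p = 0.0171, and adjusted p = 0.502 with an estimated correlation). B cell markers were again lower than in untreated libraries (median log2 change -0.51, but -0.32 without untreated 1, adjusted p = 0.0237, and adjusted p = 0.631 with an estimated correlation). This call was lost without untreated 1, Dex+IL-1B 2 or Dex+IL-1B 3 (adjusted p = 0.168, 0.0617 and 0.0524, and 0.00424 to 0.631 over all alternatives). Ighm stood at 52.8 to 56.1 CPM with both agents. Camera also called cytokine receptors lower (median -0.13, adjusted p = 0.0181). It called ATF4 and amino acid stress genes (median 0.295, adjusted p = 0.00927) and glucocorticoid receptor partners (median 0.199, adjusted p = 0.0223) higher. With an estimated correlation these lists gave adjusted p = 0.109, 0.631 and 0.631, and by fry 0.00129, 0.0852 and 0.0384. The ATF4 call was lost without untreated 1 (adjusted p = 0.131). Of 7 CD8 and NK cell markers 2 rose, 3 fell and 2 were not called, with a median of -0.80 (adjusted p = 0.198, and adjusted p = 0.00325 by fry). Camera did not call myeloid and dendritic cell markers (median -0.28, adjusted p = 0.357) or gamma-delta T and innate lymphoid markers (median -0.63, adjusted p = 0.739). Of 22 Th17 identity genes 7 rose, 6 fell and 9 were not called, with 8 higher and 7 lower when adjusted over the list alone. They had a median of -0.06, a mean of 0.23 and a test in the direction of higher values that did not pass (adjusted p = 0.384).

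Adding Dex to IL-1B, the comparison that asks what the glucocorticoid does in the presence of the cytokine, changed 38 genes, 34 higher and 4 lower, of which 13 changed at least 2-fold. Pdcd4 rose by 1.74 ± 0.11 (adjusted p = 2.24e-06), Fut4, a fucosyltransferase gene, by 1.32 ± 0.17 (adjusted p = 0.00344), Klf9 by 0.84 ± 0.10 (adjusted p = 0.00125) and Fkbp5 by 0.69 ± 0.10 (adjusted p = 0.00495). The 4 genes that fell were Sema6d (-1.21 ± 0.16, adjusted p = 0.00386), Ccl20 (-1.10 ± 0.10, adjusted p = 0.000208), the phosphatase gene Ptpn5 (-0.97 ± 0.12, adjusted p = 0.00344) and the cyclin gene Ccnd3 (-0.54 ± 0.09, adjusted p = 0.0236). The interleukin-17 genes were not called, Il17a at -0.26 ± 0.29 (adjusted p = 0.894) and Il17f at -0.17 ± 0.22 (adjusted p = 0.917), and Csf2, at 6.0 ± 1.07 CPM with IL-1B and 2.09 ± 0.469 with both, had -1.51 ± 0.49 (adjusted p = 0.512). The count was 17 without IL-1B 1, 19 without IL-1B 3, 20 without Dex+IL-1B 2 and 19 without Dex+IL-1B 3. Ccnd3 was not called without untreated 2, Dex 1, IL-1B 1, IL-1B 2, IL-1B 3, Dex+IL-1B 1, Dex+IL-1B 2 or Dex+IL-1B 3 (adjusted p = 0.0545, 0.0528, 0.0570, 0.0566, 0.0982, 0.0719, 0.0882 and 0.114, and 7.38e-06 to 0.117 over all alternatives). DESeq2 called 98 genes, edgeR on only these groups 20, where Ptpn5 had an adjusted p of 0.0518 in a range of 1.37e-08 to 0.0518, and a test against a 1.5-fold change 1.

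Other rises by the rule with Dex added to IL-1B were those of Plaur (2.06 ± 0.37, adjusted p = 0.0347), Ston1 (1.37 ± 0.23, adjusted p = 0.0170), Rapgef3 (1.27 ± 0.24, adjusted p = 0.0421) and Gpnmb (1.27 ± 0.19, adjusted p = 0.00753). Plaur was not called without untreated 2, Dex 1, IL-1B 1, IL-1B 2, IL-1B 3, Dex+IL-1B 2 or Dex+IL-1B 3 (adjusted p = 0.0509, 0.0614, 0.0975, 0.215, 0.181, 0.170 and 0.157, and 6.70e-06 to 0.215 over all alternatives). Ston1 lost its call without IL-1B 1, IL-1B 2, IL-1B 3, Dex+IL-1B 2 or Dex+IL-1B 3 (adjusted p = 0.0988, 0.114, 0.0982, 0.106 and 0.0540, and 4.50e-06 to 0.118 over all alternatives). Rapgef3 was not called without untreated 1, untreated 2, untreated 3, Dex 1, Dex 3, IL-1B 1, IL-1B 2, Dex+IL-1B 2 or Dex+IL-1B 3 (adjusted p = 0.0576, 0.0791, 0.0636, 0.0632, 0.0721, 0.239, 0.174, 0.272 and 0.204, and 0.000160 to 0.272 over all alternatives). Gpnmb lost its call without IL-1B 1, IL-1B 3, Dex+IL-1B 2 or Dex+IL-1B 3 (adjusted p = 0.0658, 0.0591, 0.0547 and 0.0540, and 4.31e-07 to 0.127 over all alternatives). On the panel, Tsc22d3 had 2.10 ± 0.51 (adjusted p = 0.257), and DESeq2 gave it an adjusted p of 0.0251, the lowest of a range of 0.0251 to 0.746. Also not called were Nfkbiz (0.62 ± 0.22, adjusted p = 0.608), Dusp1 (0.50 ± 0.14, adjusted p = 0.327) and Tnfaip3 (0.35 ± 0.13, adjusted p = 0.648). Nor were Il1r1 (0.31 ± 0.40), Il1r2 (0.28 ± 0.15), Nfkbia (0.08 ± 0.12) and Ifng (-0.76 ± 0.55). The rest of the panel was not called either, with Il23r (0.09 ± 0.18), Il22 (0.09 ± 0.68), Nr3c1 (0.08 ± 0.12) and Foxp3 (-0.02 ± 0.29).

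The list of glucocorticoid-induced genes was called higher also where Dex was added to IL-1B, and this was the one list of the comparison called with an estimated correlation. Of 20 tested 2 rose, 0 fell and 18 were not called, with 8 higher and 0 lower when adjusted over the list alone. Their median log2 change was 0.52 (adjusted p = 5.33e-19, and adjusted p = 0.0145 with an estimated correlation). Of 29 cytokines and chemokines 0 rose, 1 fell and 28 were not called, with 0 higher and 6 lower when adjusted over the list alone. The median log2 change was -0.28 (adjusted p = 4.46e-09, and adjusted p = 0.0678 with an estimated correlation), but -0.42 without Dex+IL-1B 3. Of 21 NF-kB targets 0 rose, 1 fell and 20 were not called, with 0 higher and 1 lower when adjusted over the list alone. They had a median of 0.00, a mean of 0.02 and a test in the direction of lower values that did not pass (adjusted p = 0.328). Cholesterol synthesis genes were lower (median log2 change -0.16, adjusted p = 0.000103, and adjusted p = 0.662 with an estimated correlation). ATF4 and amino acid stress genes were lower (median log2 change -0.13, adjusted p = 0.0139, and adjusted p = 0.738 with an estimated correlation). The list lost its call without IL-1B 1, IL-1B 3 or Dex+IL-1B 1 (adjusted p = 0.132, 0.271 and 0.246, and 3.18e-05 to 0.738 over all alternatives). Th17 identity genes were lower (median log2 change -0.07, but -0.015 without Dex+IL-1B 1, -0.041 without Dex+IL-1B 2 and 0.025 without the 2 libraries high in rRNA-overlapping genes, adjusted p = 0.0339, and adjusted p = 0.438 with an estimated correlation). Their call was lost without IL-1B 2 or Dex+IL-1B 1 or without the 2 libraries high in rRNA-overlapping genes (adjusted p = 0.253, 0.0785 and 0.304, and 0.0251 to 0.438 over all alternatives). Naive and homing genes were higher (median log2 change 0.06, but -0.018 to 0.21 without any one of IL-1B 1, IL-1B 2, IL-1B 3, Dex+IL-1B 1 and Dex+IL-1B 2 or without the 2 libraries high in rRNA-overlapping genes, adjusted p = 0.0472, and adjusted p = 0.738 with an estimated correlation). This call was lost without Dex 3, IL-1B 1, IL-1B 3 or Dex+IL-1B 3 or with a minimum of 1 CPM in 3 samples (adjusted p = 0.0523, 0.212, 0.295, 0.0765 and 0.0584, and 0.00169 to 0.738 over all alternatives).

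IL-1B added to Dex changed 1876 genes, 1188 higher and 688 lower, of which 258 changed at least 2-fold. Il17f rose by 3.12 ± 0.25 (adjusted p = 1.74e-05), Il17a by 2.98 ± 0.32 (adjusted p = 0.000270) and Nfkbia by 1.76 ± 0.12 (adjusted p = 2.60e-06). Klf9, raised by Dex, fell, at -0.54 ± 0.09 (adjusted p = 0.00234). The largest rises by the rule were those of Lad1 (7.40 ± 0.58, adjusted p = 1.27e-05, 5 reads over the Dex libraries), Mylk (4.39 ± 0.47, adjusted p = 0.000101) and Pdzk1ip1 (4.12 ± 0.37, adjusted p = 2.05e-05). They were followed by Il2 (3.61 ± 0.31, adjusted p = 3.28e-05), Il17f and Sema3b (3.10 ± 0.49, adjusted p = 0.00181). The largest falls by the same rule were those of Rab19 (-1.44 ± 0.26, adjusted p = 0.00334), Dysf (-1.41 ± 0.26, adjusted p = 0.00324) and Abcg3 (-1.75 ± 0.35, adjusted p = 0.00521), the latter of a multigene family. Next came Glrx (-1.33 ± 0.22, adjusted p = 0.00264), Fry (-1.32 ± 0.19, adjusted p = 0.000967) and Scml4 (-1.32 ± 0.32, adjusted p = 0.0199). Scml4 was not called without Dex 2, Dex+IL-1B 1, Dex+IL-1B 2 or Dex+IL-1B 3 (adjusted p = 0.0525, 0.0595, 0.0544 and 0.0530, and 0.000149 to 0.112 over all alternatives). The count was 909 without Dex 2, 1243 without Dex 3, 1026 without Dex+IL-1B 1 and 1205 without Dex+IL-1B 3, and a test against a 1.5-fold change called 73.

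Of the panel, with IL-1B added to Dex, Csf2 (4.33 ± 0.73, adjusted p = 0.00220), Ifng (4.03 ± 0.80, adjusted p = 0.00538) and Il22 (3.26 ± 0.87, adjusted p = 0.0239) rose, from 7, 4 and 8 reads over the Dex libraries. Nfkbiz (1.65 ± 0.23, adjusted p = 0.000932), Tnfaip3 (1.08 ± 0.13, adjusted p = 0.000360) and Il1r2 (0.85 ± 0.15, adjusted p = 0.00258) rose too. Lower was Nr3c1 (-0.40 ± 0.12, adjusted p = 0.0374). Il22 was not called without Dex 1, Dex 2 or Dex+IL-1B 2 (adjusted p = 0.0760, 0.0886 and 0.0688, and 0.00674 to 0.0886 over all alternatives). Nr3c1 lost its call without untreated 2, Dex 1, Dex 2, Dex 3, Dex+IL-1B 1 or Dex+IL-1B 3 (adjusted p = 0.0576, 0.0913, 0.0853, 0.101, 0.120 and 0.133, and 0.00586 to 0.133 over all alternatives). Not called were Tsc22d3 (-1.03 ± 0.47, adjusted p = 0.183), Il1r1 (-1.0 ± 0.38, adjusted p = 0.105) and Fkbp5 (-0.21 ± 0.10, adjusted p = 0.174). Nor were Foxp3 (-0.19 ± 0.28), Il23r (-0.09 ± 0.18) and Dusp1 (0.04 ± 0.14). Of 21 NF-kB targets 17 rose, 0 fell and 4 were not called, with 19 higher and 0 lower when adjusted over the list alone. The list had a median of 0.85 (adjusted p = 2.47e-39, and adjusted p = 0.00415 with an estimated correlation). Of 29 cytokines and chemokines 12 rose, 1 fell and 16 were not called, with 15 higher and 3 lower when adjusted over the list alone. Over the list the median was 0.60 (adjusted p = 9.07e-12, and adjusted p = 0.0162 with an estimated correlation). Of 25 interferon-stimulated genes 0 rose, 10 fell and 15 were not called, with 0 higher and 11 lower when adjusted over the list alone. As a list, these genes had a median of -0.60 (adjusted p = 4.72e-07, and adjusted p = 0.0162 with an estimated correlation). ATF4 and amino acid stress genes were called higher (median 0.256, but 0.156 without Dex 2, adjusted p = 0.025, and adjusted p = 0.847 with an estimated correlation). The ATF4 call was lost without Dex 2, Dex+IL-1B 2 or Dex+IL-1B 3 (adjusted p = 0.328, 0.115 and 0.0591, and 0.0023 to 0.847 over all alternatives). Of 22 Th17 identity genes 7 rose, 0 fell and 15 were not called, with 7 higher and 0 lower when adjusted over the list alone. Across the members the median was -0.01 (adjusted p = 0.000404, and adjusted p = 0.0861 with an estimated correlation), but -0.046 to 0.12 without any one of Dex 1, Dex 2, Dex 3, Dex+IL-1B 1, Dex+IL-1B 2 and Dex+IL-1B 3 or without the 2 libraries high in rRNA-overlapping genes, with a mean of 0.47 and a test in the direction of higher values.

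Whether one agent changed the log2 effect of the other was tested for each gene, and edgeR called 0 of 13821. At an unadjusted p under 0.05 it gave 427 genes, where 691 would be expected with no effect, DESeq2 called 1 and limma-voom 0. On the panel the values farthest from 0 were those of Il1r1 (1.22 ± 0.54), Il17f (1.10 ± 0.32), Ifng (0.84 ± 1.07, 4 reads over the Dex libraries) and Tsc22d3 (0.69 ± 0.68). None was called, and the smallest adjusted p of any gene was 0.989. Among lists, 10 were called at the preset correlation and 0 with an estimated correlation or by fry, so that a change called with Dex alone and not with Dex added to IL-1B was not shown to differ between them. For the NF-kB targets the median interaction was 0.29 (adjusted p = 1.25e-07 at the preset correlation and adjusted p = 0.252 with an estimated correlation), with 0 members called.

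The effects of one agent were also compared between libraries with and without the other, which share no library. Of the 51 genes raised by Dex alone all 51 had a positive change where Dex was added to IL-1B, at a median of 0.63 against 0.84, and 23 were called there too, where independent lists would share 0.13. Of the 34 genes raised where Dex was added to IL-1B, 33 had a positive change with Dex alone, at a median of 0.7 against 0.79. For the raised genes each median was thus larger in the comparison by which the genes were chosen. Of the 23 lowered by Dex alone, 22 had the same sign where Dex was added to IL-1B, at a median of -0.3 against -0.74. In both comparisons 3 were called, Ccl20, Sema6d and Ptpn5, against 0.01 for independent lists. The 4 lowered where Dex was added to IL-1B had a median of -1.03 there and of -1.21 with Dex alone. For these 4 the median was farther from 0 in the comparison not used to choose them. For IL-1B, 969 genes were called higher and 505 lower both without and with Dex, against 141 and 65.5 for independent lists, and 0 were called in opposite directions. Over the 13821 genes, which are not independent replicates, the log2 changes correlated at r = 0.703 (Spearman 0.68) for IL-1B and at r = 0.277 (Spearman 0.239) for Dex. Over the 9751 genes with a mean of at least 5 CPM the values were r = 0.848 (Spearman 0.816) for IL-1B and r = 0.45 (Spearman 0.305) for Dex.

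**Figure D4:**
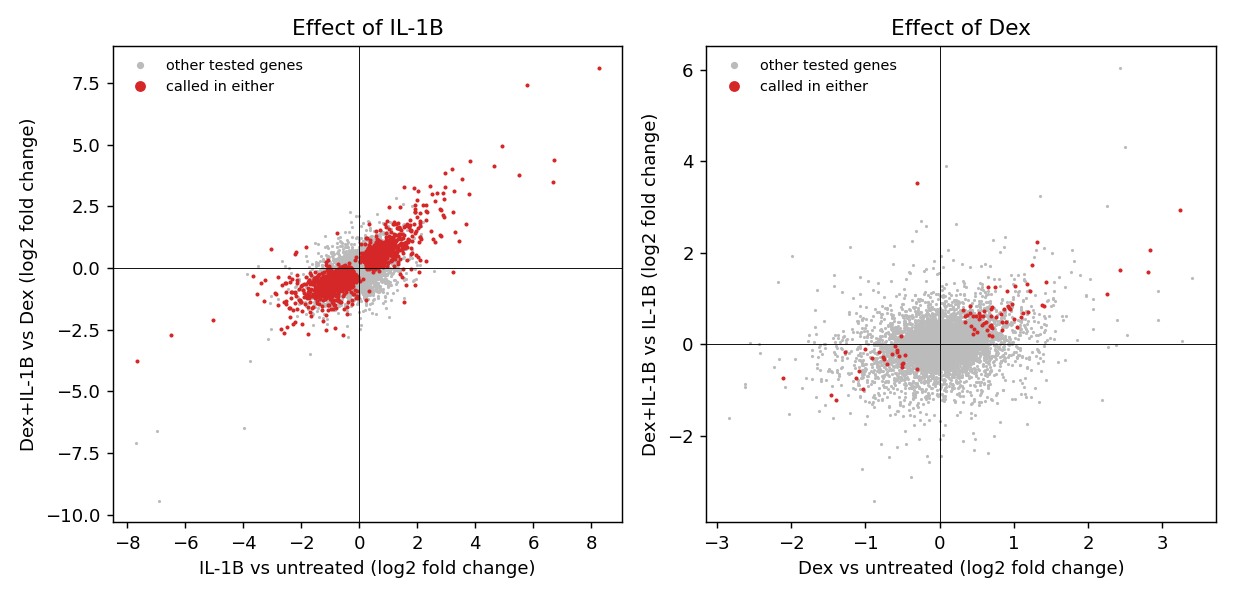
Log2 fold change of each of 13821 genes for IL-1B (left) and for Dex (right), in libraries without the other agent (x axis) and with it (y axis), genes called in either comparison in red. The correlation across all these genes is 0.703 for IL-1B and 0.277 for Dex, and across the 9751 with a mean of at least 5 CPM it is 0.848 and 0.45.

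Genes called in more than one comparison were counted with libraries in common. Of the 1644 genes raised by IL-1B, 1 was lowered where Dex was added, Ccl20, against 0.48 for independent lists. Among the 1315 lowered by IL-1B, 11 were raised by added Dex, against 3.23, Pdcd4 among them. The count of 1 was 2 without Dex 2, and the count of 11 was 7 without untreated 2, 4 without IL-1B 1, 5 without IL-1B 3, 5 without Dex+IL-1B 2 and 6 without Dex+IL-1B 3. Simulations with no effect gave 0 in each case, which leaves out the effects and so does not measure what shared libraries add to lists with real effects. Part of any excess may come from the shared IL-1B libraries, and the covariance of the log2 changes was -0.0673 against -0.0470 with no effect.

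Against the shared untreated libraries, Dex and IL-1B moved 16 genes the same way and 14 in opposite ways. Raised by both were 7, against 6.07 for independent lists, and lowered by both 9, against 2.19, Ccl3 and Ccl4 among them with the losses of their Dex calls already given. Raised by Dex and lowered by IL-1B were 9, against 4.85, and lowered by Dex and raised by IL-1B 5, against 2.74, among them Ccl20. The simulated value was again 0, with the same limit, and part of any excess in the same-way counts may come from the shared libraries. The same-way count was 3 without untreated 1, 2 without untreated 2, 29 without untreated 3, 2 without Dex 1, 129 without Dex 2, 2 without Dex 3, 26 without IL-1B 2 and 6 without Dex+IL-1B 3. The opposite-way count was 4 without untreated 1, 3 without untreated 2, Dex 1 or Dex 3, 7 without IL-1B 1, 22 without IL-1B 2, 9 without IL-1B 3 and 9 without Dex+IL-1B 3. The correlation of the log2 changes was 0.303 (Spearman 0.236) against 0.487 with no effect, and their covariance 0.0634 against 0.0432.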

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

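The test of the interaction of the NF-kB targets and both tests on B cell markers were chosen only after the result was seen.

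The NF-kB targets had a median log2 change of -0.26 with Dex alone and of 0 where Dex was added to IL-1B, a difference between cells without and with IL-1B that camera called at the preset correlation (adjusted p = 1.25e-07) and that did not pass with an estimated correlation (adjusted p = 0.252). For the 2 libraries high in rRNA-overlapping genes as the cause, the median where Dex was added to IL-1B was 0.009 without them. Its spread was 0.091, and the cause needed a fall to at most -0.13. The rule asked only that the median lie above that bound by more than the spread. With so few libraries left, the test does not exclude these 2 libraries as the cause. Without untreated replicate 1 the median with Dex alone was -0.212 with a spread of 0.083, and the list was still called (adjusted p = 2.00e-10). Both spreads are the SE of a difference in list means, not of a median. They were pooled over all libraries, those left out included. The spread of 0.083 reaches the bound of -0.13 but holds the deviation of untreated 1 itself. The test therefore does not decide whether that library is the source. That IL-1B alters the Dex response of these genes is a hypothesis that stays open: fry gave the interaction an adjusted p of 0.1391 over the lists. The test first run was the interaction of the list mean, 0.302 ± 0.105 (95% interval 0.06 to 0.544), and it was replaced by fry after this value was seen, because the list had been picked as the one with the smallest p of 26.

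B cell markers had a median of -0.54 with Dex alone and of -0.12 where Dex was added to IL-1B (interaction adjusted p = 0.000778 at the preset correlation, adjusted p = 0.255 with an estimated correlation), and that interaction, with a median of 0.42 and of 0.10 without untreated 1, lost its call without untreated 1 (adjusted p = 0.0534, and 3.78e-05 to 0.30 over all alternatives). Untreated replicate 1 had the highest Ighm (112.5 CPM) and Cd74 (103.8 CPM) of all libraries. Without it the median with Dex was -0.324, 10 of 11 members were below 0, and camera still called the list (adjusted p = 0.000263 at the preset correlation). The spread set beside that median, 0.166, is the SE of a difference in list means pooled over all libraries, untreated 1 included. This library may thus carry part of the pattern and not clearly all of it. A candidate explanation is a small share of B cells that differs between cultures, and 5 of 6 changes of Cd79a, Cd79b and Pax5 with Dex or IL-1B alone were below 0, from -0.91 ± 0.23 for Cd79a with IL-1B (adjusted p = 0.0145), the one called, to 0.37 ± 0.36 for Pax5 with IL-1B (adjusted p = 0.502). Pax5 stood at 14.7 CPM in IL-1B 2, a library high in rRNA-overlapping genes, and at 6.4 and 6.9 CPM in IL-1B 1 and 3. Untreated libraries held 5.4 to 9.6 CPM, so the positive change of Pax5 rests on IL-1B 2. The 2 explanations cannot be told apart here, because untreated 1 decides much of the untreated mean and IL-1B 2 the sign for Pax5. No other list holds members of this one, Cd74 being on the myeloid list, and a start from naive CD4+ T cells would remove most B cells.

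Other lists were called for the difference in the Dex response between cells without and with IL-1B by the same test at the preset correlation, and none with an estimated correlation or by fry. Adjusted p was 3.44e-05 for naive and homing genes (median difference 0.37), 0.00164 for glycolysis and hypoxia genes (-0.20), 0.00164 for Treg genes (-0.27) and 0.00164 for ATF4 and amino acid stress genes (-0.20). It was 0.00622 for IL-1 receptor family and signalling genes (0.20), 0.0127 for cell cycle genes (0.11), 0.0497 for Th17 identity genes (0.13) and 0.0497 for Th17 genes associated with pathogenicity (median 0.27, mean 0.07). The glycolysis and hypoxia call was lost without untreated 1, IL-1B 3 or Dex+IL-1B 1 or without the 2 libraries high in rRNA-overlapping genes (adjusted p = 0.266, 0.0567, 0.0738 and 0.137, and 2.02e-05 to 0.434 over all alternatives). The Treg call was lost without untreated 1 (adjusted p = 0.0534, and 1.00e-05 to 0.365 over all alternatives). That of ATF4 and amino acid stress genes was lost without untreated 1 or IL-1B 3 (adjusted p = 0.123 and 0.0525, and 9.92e-06 to 0.434 over all alternatives). The IL-1 receptor family call was lost without untreated 1 or IL-1B 3 (adjusted p = 0.0534 and 0.0641, and 0.00324 to 0.252 over all alternatives). That of cell cycle genes was lost without untreated 1, IL-1B 2 or Dex+IL-1B 1 or without the 2 libraries high in rRNA-overlapping genes (adjusted p = 0.0534, 0.179, 0.142 and 0.510, and 0.00334 to 0.510 over all alternatives). The Th17 identity call was lost without untreated 1, Dex 1, IL-1B 1, IL-1B 3, Dex+IL-1B 1 or Dex+IL-1B 3 or with median-ratio scaling (adjusted p = 0.123, 0.104, 0.131, 0.217, 0.0731, 0.0687 and 0.0539, and 0.00406 to 0.30 over all alternatives). That of the pathogenicity genes was lost without untreated 1, untreated 3, Dex 1, Dex 2, IL-1B 3, Dex+IL-1B 1 or Dex+IL-1B 3 or with median-ratio scaling (adjusted p = 0.0534, 0.0693, 0.0932, 0.105, 0.153, 0.0731, 0.0969 and 0.0553, and 0.00663 to 0.255 over all alternatives). These median differences also moved. That of naive and homing genes was 0.11 without untreated 1, 0.18 without Dex 3 and 0.24 without Dex+IL-1B 1. For glycolysis and hypoxia genes it was -0.12 to -0.05 without any one of untreated 1, Dex 3, IL-1B 2 and Dex+IL-1B 1 or without the 2 libraries high in rRNA-overlapping genes. For Treg genes it was -0.11 without untreated 1, and for pathogenicity genes 0.18 without Dex 2. For ATF4 and amino acid stress genes it was -0.32 to -0.086 without any one of untreated 1, untreated 3, Dex 2 and Dex 3. For cell cycle genes it was 0.039 without IL-1B 2, 0.045 without Dex+IL-1B 1 and 0.014 without the 2 libraries high in rRNA-overlapping genes. For Th17 identity genes it was 0.043 to 0.082 without any one of untreated 1, Dex 1, Dex 3, IL-1B 1 and IL-1B 3. The number of lists called was 10 with all libraries, 2 without untreated replicate 1 and 6 without IL-1B replicate 3.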

How the results depend on the processing

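The fit without the 2 libraries high in rRNA-overlapping genes and the split of simulated genes by CPM were chosen only after the result was seen. The counts of genes for IL-1B and for both agents against untreated or Dex cells stayed within 1.5 times under every other tool, scaling and filter, and no named gene changed sign between fits where either called it. No list called in either fit reversed the direction of its test, but medians near 0 changed sign for cholesterol synthesis genes with Dex, for naive and homing genes and Th17 identity genes where Dex was added to IL-1B, and for Th17 identity genes where IL-1B was added to Dex. DESeq2 called 281 genes for Dex against untreated, 98 for Dex added to IL-1B and 1 for the interaction, with 5 genes raised by IL-1B and lowered by added Dex, 29 the reverse, and 92 and 38 for Dex and IL-1B the same and opposite ways. No low-count filter gave 138 for Dex and 41 the same way. A fit to only the groups compared gave 20 for Dex added to IL-1B, 5 lowered by IL-1B and raised by added Dex and 8 the same way. The test against a 1.5-fold change gave 7, 127, 172, 1 and 73 genes in the 5 comparisons (Dex, IL-1B and both against untreated, both against IL-1B, both against Dex) and 0 for each of the shared counts, fewer by its own construction. Without the 2 libraries Dex gave 266 genes, with 67 the same way and 43 opposite. With an estimated correlation 5, 1, 2, 1, 3 and 0 lists were called in the 5 comparisons and the interaction, and fry called 7, 9, 8, 1, 7 and 0. The cause of these moves was not tested.

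Leaving out each library in turn gave 16 to 253 genes for Dex, 1609 to 3389 for IL-1B, 1310 to 3402 for both against untreated, 17 to 46 for both against IL-1B, 909 to 2611 for both against Dex and 0 to 0 for the interaction. The shared counts ran from 1 to 2 (raised by IL-1B, lowered by added Dex), 4 to 11 (the reverse), 2 to 129 (same way) and 3 to 22 (opposite). For the named genes, over all alternatives, 85, 81, 108, 61 and 113 values lost a call in the 5 comparisons and 70, 47, 19, 13 and 20 gained one. Lists called ran from 10 to 16, 7 to 10, 6 to 12, 4 to 7 and 4 to 6 in the comparisons and from 2 to 13 for the interaction.

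The replicate numbers did not pair the libraries: over 18 same-numbered pairs the correlation of deviations was -0.21 to 0.18, with 5 above 0.1, and the best match in another group had the same number in 17 of 36 cases. With the number as a block 61, 2783, 2431, 31, 1778 and 0 genes were called in the comparisons and the interaction. With the block the cholesterol synthesis list was not called with Dex (adjusted p = 0.0504), and 5 list calls were gained. Depth limits the genes with few reads: in simulated data the interaction was called for 3.6% of 28 genes changed 2-fold with a mean under 5 CPM and for 84.6% of 39 with at least 5 CPM. Simulated genes varied independently, without differences between libraries that many genes share. In the real data the interaction gave 427 genes at an unadjusted p under 0.05, fewer than the 691 expected with no effect. These shares may therefore be too high for the real libraries.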

Other observations

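The split test of the interaction was chosen only after the result was seen.

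IL-1B alone also moved genes of survival and inhibition that the report does not describe. Of 21 BCL2 family and death receptor genes 4 rose, 5 fell and 12 were not called, against 5 higher and 5 lower when adjusted over the list alone. The survival gene Bcl2l1 (1.68 ± 0.20, adjusted p = 0.000311) was higher, and the killing ligand Fasl (-2.71 ± 0.56, adjusted p = 0.00451) and the death genes Bad (-0.73 ± 0.12, adjusted p = 0.00126) and Bcl2l11 (-1.22 ± 0.23, adjusted p = 0.00329) were lower. The list as a whole was not called (adjusted p = 0.622). Of 14 coinhibitory receptor and adenosine genes 2 rose, 5 fell and 7 were not called, against 2 higher and 5 lower when adjusted over the list alone. Higher was Cd200 (1.16 ± 0.11, adjusted p = 3.48e-05) and lower were Pdcd1 (-0.96 ± 0.17, adjusted p = 0.00245), Nt5e (-1.28 ± 0.18, adjusted p = 0.000794) and Lag3 (-0.56 ± 0.09, adjusted p = 0.00154). The list was not called (adjusted p = 0.457).

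With IL-1B, of 25 T cell activation genes 2 rose, 4 fell and 19 were not called, against 2 higher and 5 lower when adjusted over the list alone. The early activation marker Cd69 (1.31 ± 0.08, adjusted p = 7.28e-07) was higher and Fos (-1.43 ± 0.19, adjusted p = 0.000525), Nfatc1 (-0.71 ± 0.11, adjusted p = 0.00114) and Egr3 (-0.84 ± 0.14, adjusted p = 0.00133) were lower (list adjusted p = 0.732). Of 7 CD8 and NK cell markers 0 rose, 3 fell and 4 were not called, against 1 higher and 3 lower when adjusted over the list alone. The cytotoxic genes Nkg7 (-1.02 ± 0.19, adjusted p = 0.00249) and Prf1 (-1.22 ± 0.28, adjusted p = 0.00726) and the receptor Klrd1 (-0.83 ± 0.16, adjusted p = 0.00302) were lower (list adjusted p = 0.223, and 0.00429 by fry). Of 18 IL-1 receptor family and signalling genes 4 rose, 4 fell and 10 were not called, and the list as a whole was not called. Il1rn, which encodes the natural antagonist of the IL-1 receptor, was among the 4 that rose, at 2.88 ± 0.26 (adjusted p = 2.47e-05).

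Tests argued against 2 technical sources of the number of genes changed by IL-1B, the 2 libraries high in rRNA-overlapping genes and gene length. They did not cover a difference in composition shared by all libraries with IL-1B. TMM factors were 0.908 to 0.997 in the libraries with IL-1B, alone or with Dex, and 1.024 to 1.044 in the others. Of the genes called with IL-1B alone, 98.1% had the same sign in Dex+IL-1B replicates 2 and 3 against the Dex libraries, where neither library high in rRNA-overlapping genes takes part. Transcript length correlated with the log2 change at a Spearman value of 0.074 over genes, under the 0.1 set as the limit. A hypothesis of a biological effect of IL-1B is left open by these tests, which were run on the same data.

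Other splits of the libraries were tried. Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. For Dex against untreated 2 of the 10 splits gave as many genes as the real one, with 74 for the real one and 257 for the highest other, untreated replicates 1 and 2 and Dex replicate 2 against the rest, which points to a structure of the samples other than the treatment. In each of the other comparisons 1 split, the real one, gave as many, with 2959, 2511, 38 and 1876 genes for IL-1B against untreated, both against untreated, both against IL-1B and both against Dex, and 0 as the highest other. For the interaction the real count was 0, so that all 100 of the 100 splits drawn gave as many by construction, with 554 as the highest other, and this test says nothing about chance.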
